A study of Homo sapiens with 6 samples.

How the data were processed

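Gene expression was measured in MDA-MB-231, an established human breast cancer cell line of the triple-negative kind, after transfection with a small interfering RNA (siRNA) against SDC1 or with a negative control siRNA. SDC1 encodes syndecan-1, a transmembrane proteoglycan that carries heparan sulfate chains. The 6 samples fall into 2 groups of 3, and the series design describes the replicates of a group as independent. Biotin-labelled cRNA was hybridised to 6 Affymetrix arrays, 1 per sample. Tools and steps other than RMA (robust multi-array average), which the submitters' processing notes name with no version, are not given in the sources used here.

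The values used are log2 expression values as deposited by the authors, 54675 probe sets on each of the 6 arrays. Every probe set had a median over the 6 arrays within 1e-06 of 0, so the deposited log2 values are relative to that median. This centring is not stated in the labels and was read from the values. It removes expression levels and leaves the difference between groups unchanged. The base of the logarithm was taken as 2 because the numbers move in the steps that single-precision log2 values between 2 and 16 leave after subtraction. The medians of the arrays lay between -0.01 and 0.01 and their standard deviations between 0.186 and 0.208. No pair of arrays held identical values.

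Probe sets were named from the platform annotation supplied with the series. It gave a single gene for 41097 probe sets, several for 1801 and none for 11777. The manufacturer's 62 control probe sets were left out of the tests. The gene identifiers of 41043 single-gene probe sets were found in a RefSeq table of human assembly GRCh38.p14, used only for current symbols and for which genes neighbour each other. The array annotation names no build, so no coordinates are given. In all 19775 genes were tested. Probe sets that the annotation leaves unnamed or ties to several genes entered only the fit over all probe sets, and genes that only they would measure were not analysed here.

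Before the data were examined, each gene was to be represented by its probe set of highest mean, with a filter on dim genes as an alternative. Centred values carry no mean, so a coarse brightness class was used in its place. The numeric step of the 3 arrays at or above the median puts a probe set at a log2 level between 2 and 4, between 4 and 8, or between 8 and 16. The classes held 11804, 25928 and 16943 probe sets. Of the brightest class, 15.7% had a step coarser than such a level leaves, so some probe sets are placed too high. A gene's value was the mean of its single-gene probe sets in its brightest class, and probe sets ending in _x_at were used only where a gene had no other. Background signal was not among the values, so no detection call was made.

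Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), as SDC1 siRNA minus control siRNA, with no covariates and with Benjamini-Hochberg adjustment at 0.05. Gene lists, 29 in number and holding 1093 genes of which 1008 were measured, were written before the data were examined. One list, with the single genes in it, is kept in the tests and in the counts over lists but is not reported here. The lists cover heparan sulfate biology, adhesion, signalling, stress, metabolism, growth and markers of other cell types. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. The counts of changed members are given over all genes tested and adjusted over the list alone. Genes named in the text follow a rule fixed before the data were examined. It takes SDC1, the 10 largest rises and 10 largest falls among genes past the threshold whose groups of arrays did not overlap, up to 4 members of each list by lowest p, and 20 genes chosen for their link to syndecan or adhesion. Genes named outside this rule are said to have been chosen after their values were seen.

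Control probe sets were compared with an exact permutation test, whose smallest possible 2-sided p is 0.1 for 3 against 3 arrays. The poly-A spike-in controls, added to RNA before labelling, parted the arrays into 2 batches that both hold both groups. Their mean was between 0.39 and 0.68 in control replicate 1 and SDC1 siRNA replicates 1 and 2, and between -0.47 and -0.43 in the other arrays. Values within these batches are given beside the pooled ones, a choice made after seeing the data. The labels name no batch.

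Precision is limited by the number of arrays. The median standard error of a log2 fold change was 0.075 and the median standard deviation within a group 0.092. On simulated data with the spread of these arrays, the fit recovered 62 of 100 genes changed by 0.5 on the log2 scale and 94 of 100 changed by 1, and called 2 of the unchanged genes among the 19775. Only 200 genes were changed there, far fewer than the 5571 called in the real data. The adjustment depends on that share, so the recovery need not be the same here. The alternatives cover replicate and batch blocks, the prior, dim genes, thresholds, the choice of probe sets, normalization, array weights, set tests and leaving out each array. The planned trend on mean expression became a trend on the brightness class. Figures were drawn with matplotlib 3.10.9. No sequence of either siRNA was used, so targets of the siRNAs other than SDC1 were not searched.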

Results

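The data comprised 6 arrays of MDA-MB-231 cells, 3 from cultures given the SDC1 siRNA and 3 from cultures given the control siRNA, and the comparison asked which genes change when syndecan-1 is silenced. Values are log2 expression relative to the median of each probe set over the 6 arrays, so changes but not levels can be read from them. Fold changes are SDC1 siRNA over control siRNA, with the standard error (SE) of the limma fit and n = 3 per group.

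SDC1 transcript was strongly reduced. Its mean was -1.24 ± 0.16 (SD, n = 3) after SDC1 siRNA and 1.18 ± 0.13 (SD, n = 3) after control siRNA, a log2 fold change of -2.42 (SE 0.097, adjusted p = 2.05e-06) that left 18.7% of the control transcript. Both SDC1 probe sets fell, to 22.7% and 15.3% of control. The fold change was -2.28 in the first spike-in batch and -2.63 in the second. Among the other syndecans, SDC4 fell by 0.59 on the log2 scale (SE 0.090, adjusted p = 0.00136), whereas SDC2 (log2 fold change -0.10, adjusted p = 0.283) and SDC3 (0.02, adjusted p = 0.898) did not pass the test.

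Silencing was accompanied by a broad change in expression. Of 19775 genes, 5571 (28.2%) passed the threshold, 2574 higher and 2997 lower after SDC1 siRNA. At 1.5-fold or more the numbers were 613 higher and 772 lower, and at 2-fold or more 136 higher and 226 lower. Large changes leaned towards loss, with 25 genes lower and 3 higher by at least 4-fold. The first principal component held 66.4% of the variance and parted the groups. The arrays of the groups did not overlap for 5551 of the 5571 changed genes, and for 41.8% of all genes against 10% by chance. Of 2670 genes called within the first spike-in batch alone 2594 had the same sign in the second, and of 1895 called within the second 1874 had the same sign in the first, against 70.9% of all genes with the same sign in both. Each of these batches holds only 1 array of one of the groups. The share of changed genes was 4.89% in the dimmest brightness class and 41.5% in the brightest.

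**Figure D1:**
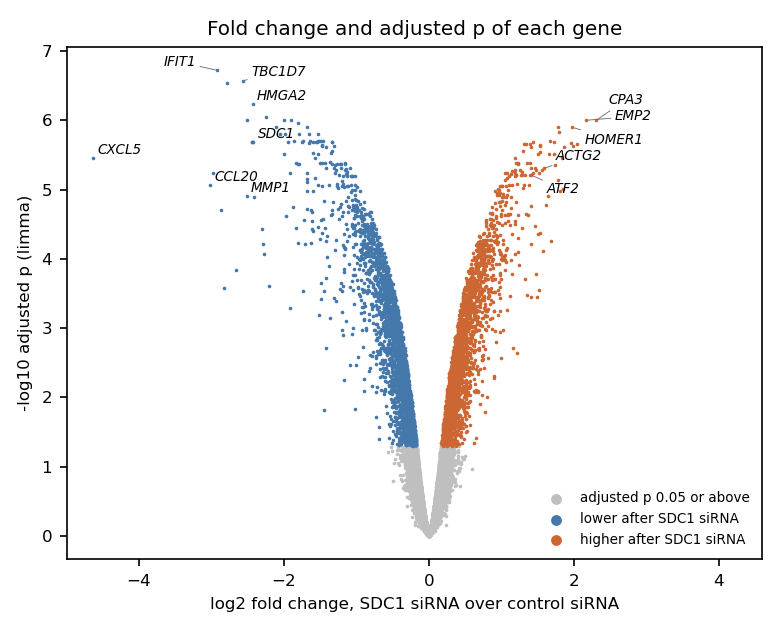
Each point is 1 of 19775 genes, with the log2 fold change (SDC1 siRNA over control siRNA, 3 arrays each) on the horizontal axis and -log10 of limma's adjusted p on the vertical axis. Blue points are the 2997 genes lower and orange points the 2574 genes higher past 0.05, and the longest tail is on the lower side, out to CXCL5 at -4.64.

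The 10 largest falls included chemokines and interferon-stimulated genes. CXCL5, a chemokine that attracts neutrophils, fell by 4.64 on the log2 scale (SE 0.22, adjusted p = 3.56e-06), a 24.9-fold loss. That size depends on the probe sets read, as CXCL5 was at -3.43 with all of them averaged and -2.61 with the class from all 6 arrays. Its dimmest probe set gave -0.59 (adjusted p = 0.0902), and its brightest, a cross-hybridising one left out of the gene value, gave -5.05. CXCL5 was followed by CCL20, a chemokine for lymphocytes and dendritic cells, at -3.02 (SE 0.17), and by the serine protease inhibitor SERPINB4 at -2.98 (SE 0.16). IFIT1 (-2.92, SE 0.058) and IFIT3 (-2.79, SE 0.067) encode antiviral proteins induced by interferon. SERPIND1, the thrombin inhibitor heparin cofactor II, was at -2.86 (SE 0.19), and CSF3, the granulocyte colony-stimulating factor, at -2.83 (SE 0.31). SCG5, a secretory granule chaperone, TBC1D7, a subunit of the TSC complex that restrains mTOR signalling, and the collagenase MMP1 were at -2.67, -2.56 and -2.51, with a dim TBC1D7 probe set at -0.07 (adjusted p = 0.678). Adjusted p for these 10 genes ran from 1.90e-07 for IFIT1 to 0.000262 for CSF3.

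The largest rise was that of CPA3, a carboxypeptidase best known from mast cells, at 2.31 (SE 0.074), a 4.96-fold gain. EMP2, an epithelial membrane protein, rose by 2.17 (SE 0.067) and THG1L, an enzyme of histidine tRNA maturation, by 2.05 (SE 0.086). The monocarboxylate transporter family members SLC16A9 and SLC16A14 rose by 1.99 and 1.85. HOMER1, a scaffold protein, KRCC1, the mitochondrial topoisomerase TOP1MT, the ferrireductase STEAP3 and CCDC190 rose by 1.98, 1.96, 1.87, 1.84 and 1.80, with a dim TOP1MT probe set at -0.06 (adjusted p = 0.715). The highest adjusted p of these 10 was 1.04e-05, for CCDC190.

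**Figure D2:**
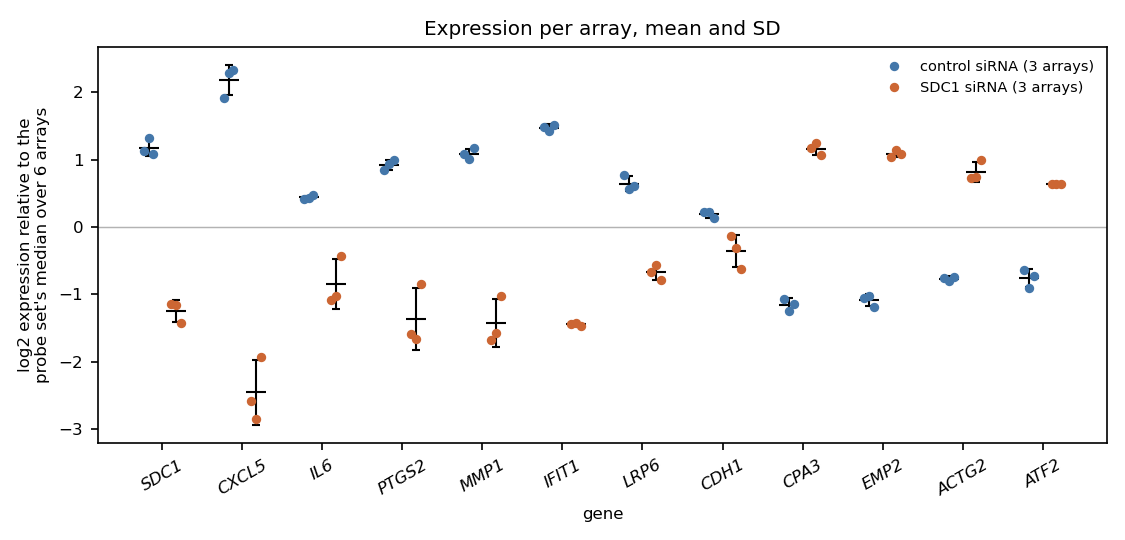
Log2 expression relative to the probe set's median over 6 arrays (vertical axis) for 12 genes (horizontal axis), with a dot per array and bars for the mean and SD of 3 arrays per group. SDC1 changed by -2.42, CXCL5 by -4.64 and CPA3 by 2.31, and no control array lies among the SDC1 siRNA arrays for any gene shown.

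Interferon-stimulated genes fell as a group. Of 52 measured members, 31 fell and 3 rose (31 and 5 adjusted over the list alone), with a median log2 fold change of -0.37, and camera gave an adjusted p = 6.45e-10. The list's adjusted p was 0.292 with an estimated correlation. IFIT2 fell by 2.51 (SE 0.079) and OASL, an oligoadenylate synthetase-like protein, was at -2.24 (SE 0.065). The genes that rose were EIF2AK2 (0.59), the double-stranded RNA-activated kinase, TRIM14 (0.56) and BST2 (0.53). IFNB1, which encodes interferon beta and is the only interferon gene in the list, was at 0.04 (adjusted p = 0.818). The double-stranded RNA sensors RIGI and IFIH1 fell by 1.19 and 1.80. These 6 genes were named after their values were seen. The median of the list was -0.39 in the first spike-in batch and -0.44 in the second. No untransfected cells were analysed here, so a loss in one group cannot be told from a gain in the other.

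Cytokines and chemokines were lower. In this list of 34 measured genes 19 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.36 (-0.36 and -0.37 within the batches) and a camera adjusted p = 7.67e-07, against an adjusted p of 0.292 with an estimated correlation. Beside CXCL5 and CCL20, the interferon-induced chemokine CXCL11 fell by 2.45 (SE 0.099), while its dimmer probe set gave -1.64. IL1A fell by 2.41 (SE 0.15) on its bright probe set, while its dimmer probe set gave 0.21 (adjusted p = 0.176). IL6, a driver of STAT3 signalling, fell by 1.29 (SE 0.16, adjusted p = 0.000406). The member that rose, named after its value was seen, was CSF1 at 0.61. For CXCL5, CCL20, CSF3 and IL1A the SD among SDC1 siRNA arrays was 0.48, 0.39, 0.77 and 0.34, above the 0.092 of the median gene.

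The STAT3 and NF-kB list held 37 measured genes, of which 14 fell and 4 rose (20 and 6 adjusted over the list alone). Its median was -0.20 (-0.26 and -0.18 within the batches) and camera's adjusted p 0.0215, with an adjusted p of 0.292 when the correlation was estimated. The receptor chain IL6R fell by 1.83 (SE 0.088), or by 1.11 with all probe sets averaged, and its partner IL6ST rose by 0.86 (SE 0.061). SOCS4, of the family of cytokine signalling suppressors, rose by 1.31 (SE 0.077), and TNFAIP2 fell by 0.77 (SE 0.057). STAT3 itself was at 0.17 (SE 0.058, adjusted p = 0.0610), with an adjusted p of 0.0358 under a robust prior with a trend on brightness and of 0.0482 without the dimmest class.

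Genes of the unfolded protein and amino acid stress response fell together, 22 of 40 measured against 1 that rose (23 and 1 adjusted over the list alone). The median was -0.27 (-0.31 and -0.27 within the batches) and the camera adjusted p 3.84e-07, with an adjusted p = 0.081 with an estimated correlation. CTH, an enzyme of cysteine synthesis, fell by 1.10 (SE 0.087) and DNAJB9, a chaperone of the endoplasmic reticulum, by 1.07 (SE 0.058). CHAC1, which degrades glutathione, and HERPUD1, a protein of endoplasmic reticulum-associated degradation, fell by 0.76 and 0.65. In contrast, heat shock proteins did not pass camera (adjusted p = 0.300), with 5 of 16 higher, 3 lower (7 and 4 adjusted over the list alone) and HSPB1 at 0.68 and HMOX1 at -0.59.

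Apoptosis genes were also lower, 17 of 42 against 5 that rose, the same numbers adjusted over the list alone. The median was -0.12 (-0.11 and -0.14 within the batches) and camera's adjusted p 0.0180, with an adjusted p = 0.292 with an estimated correlation and 0.0547 without SDC1 siRNA replicate 3. The list holds both promoters and inhibitors of cell death. BCL2A1, an inhibitor of cell death, fell by 1.91 (SE 0.10), as did the inflammatory caspase CASP1 by 1.57, the death receptor TNFRSF10A by 1.12 and the death inducer PMAIP1 by 1.02. Among p53 targets and cell cycle inhibitors 12 of 32 were lower and 4 higher (14 and 5 adjusted over the list alone, adjusted p = 0.0850), with the cell cycle inhibitor CDKN1A at -1.12 (SE 0.075) and the RNA-binding p53 target ZMAT3 at 0.98 (SE 0.063). RRM2B rose by 0.73.

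Adhesion and cytoskeleton genes moved in both directions. In the actin and focal adhesion list of 53 genes 17 rose and 10 fell (17 and 12 adjusted over the list alone), and camera found no shift (adjusted p = 0.448). Its median (-0.03) and mean (0.11) differed in sign, and camera's direction was upward. The smooth muscle actin ACTG2 rose by 1.59 (SE 0.081), 3.00-fold, though its dimmer probe set gave 0.08 (adjusted p = 0.562). The actin-binding protein TAGLN rose by 1.36, the membrane linker RDX by 1.12 and the myosin light chain MYL9 by 0.72, for which single probe sets gave 1.35 and 0.09. FERMT2, an integrin activator, fell by 0.71. VCL, the focal adhesion protein vinculin, was at -0.21 (adjusted p = 0.104), and -0.33 (adjusted p = 0.00973) with all probe sets averaged or -0.27 (adjusted p = 0.0224) with the spike-in batch as a block.

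Cadherins and junction proteins had 11 of 39 members lower and 2 higher (13 and 2 adjusted over the list alone), short of the threshold as a list (adjusted p = 0.0850, and 0.0473 without control replicate 2). The tight junction protein CLDN1 fell by 1.42 (SE 0.12), JUP and DSG2 of the desmosome by 0.61 and 0.48, and OCLN by 0.46. The epithelial cadherin CDH1 fell by 0.55 (SE 0.11, adjusted p = 0.00676) on its bright probe set, while its dimmer one gave -0.17 (adjusted p = 0.36). The mesenchymal cadherin CDH11 rose by 0.45 (SE 0.10, adjusted p = 0.0108), with other probe sets up to 1.25. Integrins had 1 of 19 higher and 4 lower, unchanged when adjusted over the list alone (adjusted p = 0.139), led by ITGB2 at -1.44 (SE 0.070) and ITGA5 at -0.62. ITGA2 fell by 0.54 and ITGA1 by 0.37, while a dim ITGA1 probe set gave 0.22 (adjusted p = 0.202). The ITGA1 call was lost with all probe sets averaged (-0.24, adjusted p = 0.0564).

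The list for epithelial to mesenchymal transition had 8 of 33 higher and 6 lower (10 and 6 adjusted over the list alone, adjusted p = 0.825), with a median of -0.01, a mean of 0.01 and an upward direction in camera. The transforming growth factor receptor chains TGFBR2 and TGFBR1 moved apart, at -1.58 (SE 0.087) and 0.95 (SE 0.076). VIM, encoding the mesenchymal filament vimentin, fell by 0.62 and INHBA by 0.68, and the transcription factor TCF4 rose by 0.51 (adjusted p = 0.00557). Epithelial and luminal markers had 7 of 34 higher and 3 lower (7 and 5 adjusted over the list alone, adjusted p = 0.342), among them KRT80 at 1.05, CD24 at 0.71, GATA3 at 0.44 and XBP1 at -0.35, the mean of probe sets at -0.79 and 0.09.

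Matrix genes went both ways, with 10 of 50 higher and 11 lower (11 and 14 adjusted over the list alone, adjusted p = 0.702). The antiangiogenic matrix protein THBS2 rose by 1.18 (SE 0.061) and CCN3 by 0.63, while CCN1 and CCN2, which YAP signalling induces, fell by 0.68 and 0.79. Extracellular proteases and inhibitors had 5 of 47 higher and 13 lower (6 and 15 adjusted over the list alone, adjusted p = 0.145). Besides MMP1, the sheddase ADAM19 fell by 1.31 (SE 0.056), although its other probe set gave 0.03 (adjusted p = 0.892), the cathepsin CTSS by 0.92 and the urokinase PLAU by 0.81. The gelatinases MMP2 and MMP9 were both at 0.06 (adjusted p = 0.676 and 0.665).

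Among the other heparan sulfate proteoglycan cores 1 of 19 was higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.475). TGFBR3, the betaglycan co-receptor, fell by 1.05 (SE 0.079) and the hyaluronan receptor CD44 by 0.68, and GPC5 rose by 0.37. Enzymes that make or trim heparan sulfate had 8 of 32 higher and 5 lower, with equal counts adjusted over the list alone (adjusted p = 0.448). SLC35D1, a nucleotide sugar transporter, rose by 1.20 (SE 0.077), HPSE, the heparanase that cleaves heparan sulfate, by 0.90 (SE 0.070) and the epimerase GLCE by 0.62. The chain polymerase EXT2 fell by 0.55 (SE 0.056), and its partner EXT1 was at -0.20 (adjusted p = 0.0897), or -0.25 (adjusted p = 0.0343) with the spike-in batch as a block and -0.42 (adjusted p = 0.00493) with the class from all 6 arrays, its probe sets ranging from -0.42 to 0.02.

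Developmental signalling lists did not shift as wholes. In the Wnt list 5 of 52 were higher and 6 lower, unchanged when adjusted over the list alone (adjusted p = 0.655), with a median of 0.04, a mean of -0.01 and an upward direction in camera. LRP6, a Wnt co-receptor, fell by 1.32 (SE 0.084) on its bright probe set, whereas its dimmer ones gave 0.03 and 0.02 (adjusted p = 0.813 and 0.939). DVL3 fell by 1.19, though its cross-hybridising probe set gave 0.04 (adjusted p = 0.782). DKK3 fell by 0.62, the mean of probe sets at -1.14 and -0.10 (adjusted p = 0.54 for the latter), and ZNRF3 rose by 0.82. Notch, Hedgehog and stem cell genes had 5 of 39 higher and 7 lower (6 and 9 adjusted over the list alone, adjusted p = 0.478). Of these, the pluripotency factor KLF4 fell by 1.22 (SE 0.062), HES4 by 0.79 and the drug efflux pump ABCG2 by 0.68, while RBPJ, the DNA-binding partner of Notch, rose by 1.00 (SE 0.074). NOTCH1 was at -0.06 (adjusted p = 0.649).

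Heparin-binding growth factors and receptors had 12 of 44 higher and 7 lower (14 and 7 adjusted over the list alone, adjusted p = 0.406). Midkine, MDK, rose by 1.42 (SE 0.076), PDGFC by 1.09 (SE 0.065) and NRG1 by 0.75, whose probe sets ranged from -0.21 (adjusted p = 0.159) to 1.71, and EREG fell by 0.99, while its dimmer probe set gave 0.20 (adjusted p = 0.332). Immediate early and MAPK feedback genes had 16 of 38 lower and 8 higher (17 and 9 adjusted over the list alone, adjusted p = 0.0850). HMGA2, a chromatin architectural protein, fell by 2.43 (SE 0.065) on its bright probe set, and dimmer HMGA2 probe sets reached 0.59. KLF6 and KLF10 fell by 0.66 and 0.57. PHLDA1 rose by 0.67, the mean of probe sets from 0.18 (adjusted p = 0.140) to 1.34. Prostaglandin and ATF/CREB genes had 6 of 27 higher and 9 lower, the same when adjusted over the list alone (adjusted p = 0.702). PTGS2, the inducible cyclooxygenase, fell by 2.29 (SE 0.19), HPGD, which degrades prostaglandins, rose by 0.59, ATF2 rose by 1.40 (SE 0.075, with 0.56 and 0.02 for its dimmer probe sets) and CREB1 fell by 0.57.

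Genes of lipid synthesis and of hypoxia and glycolysis rose as groups. Of 29 measured genes of cholesterol and fatty acid synthesis 12 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.23 (0.30 and 0.10 within the batches). Camera's adjusted p was 0.00283, and the adjusted p was 0.620 with an estimated correlation. STARD4, a sterol carrier, rose by 0.85 (SE 0.096), TM7SF2 by 0.57, ELOVL6 by 0.52 and PMVK by 0.51. In the hypoxia and glycolysis list 13 of 37 rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 0.15 (0.15 and 0.08 within the batches). Its adjusted p was 0.0128, or an adjusted p of 0.543 with an estimated correlation. PDK1, a kinase that inhibits pyruvate dehydrogenase, rose by 1.02 (SE 0.083), the carbonic anhydrase CA12 by 0.90 and BNIP3 by 0.63. The glucose transporter SLC2A1 fell by 0.63. Cell cycle genes had 15 of 63 higher and 12 lower (19 and 12 adjusted over the list alone, adjusted p = 0.136), with the mitotic motors KIF11 and KIF20A at 1.05 and 0.67, PRC1 at 0.87 and the replication factor GINS2 at 0.66, though at 0.11 and -0.14 on dimmer probe sets.

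Few ribosomal protein genes or markers of other cell types changed. Ribosomal proteins had 3 of 34 higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.132). The lowest p was that of RPL22 at 0.45, for which 3 cross-hybridising probe sets lay between -0.14 and -0.12. The RPL22 call was lost with all probe sets averaged (0.10, adjusted p = 0.221) and with _x_at probe sets (adjusted p = 0.235). RPS24 rose by 0.45, the mean of probe sets at 1.03 and -0.12, and RPL35 by 0.20, a call lost with any array left out and with the replicate block, and RPL7 fell by 0.39 on a probe set outside the brightest class, while 2 others gave 0.13 and 0.14. RNA interference genes had 6 of 15 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.496), with a median of -0.02, a mean of 0.06 and an upward direction in camera. TARBP2 rose by 0.56, TNRC6A by 0.39, PRKRA by 0.35 and AGO4 by 0.35, but PRKRA was at 0.11 (adjusted p = 0.337) with all probe sets averaged. The TNRC6A value was the mean of probe sets from 0.01 (adjusted p = 0.922) to 0.81. That of AGO4 was the mean of probe sets from 0.11 (adjusted p = 0.452) to 0.81. Leukocyte markers had 1 of 23 higher and 2 lower (adjusted p = 0.702), namely CSF1R at 0.32, LAPTM5 at -0.92 and CD14 at -0.46. Endothelial and fibroblast markers had 1 of 21 higher and 3 lower (adjusted p = 0.412), namely RGS5 at 0.25, ESAM at -0.78, COL1A1 at -0.77 and ACTA2 at -0.27. The COL1A1 value is that of 1 probe set, and its others ranged from -1.23 (adjusted p = 0.000182) to 0.18 (adjusted p = 0.11). The RGS5 value rests on 1 probe set at 0.99, the others ranging from -0.09 to 0.10, and its call was lost without SDC1 siRNA replicate 2 and with all probe sets averaged, and a dim ACTA2 probe set gave 0.21 (adjusted p = 0.309). Both counts were the same adjusted over the list alone.

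**Figure D3:**
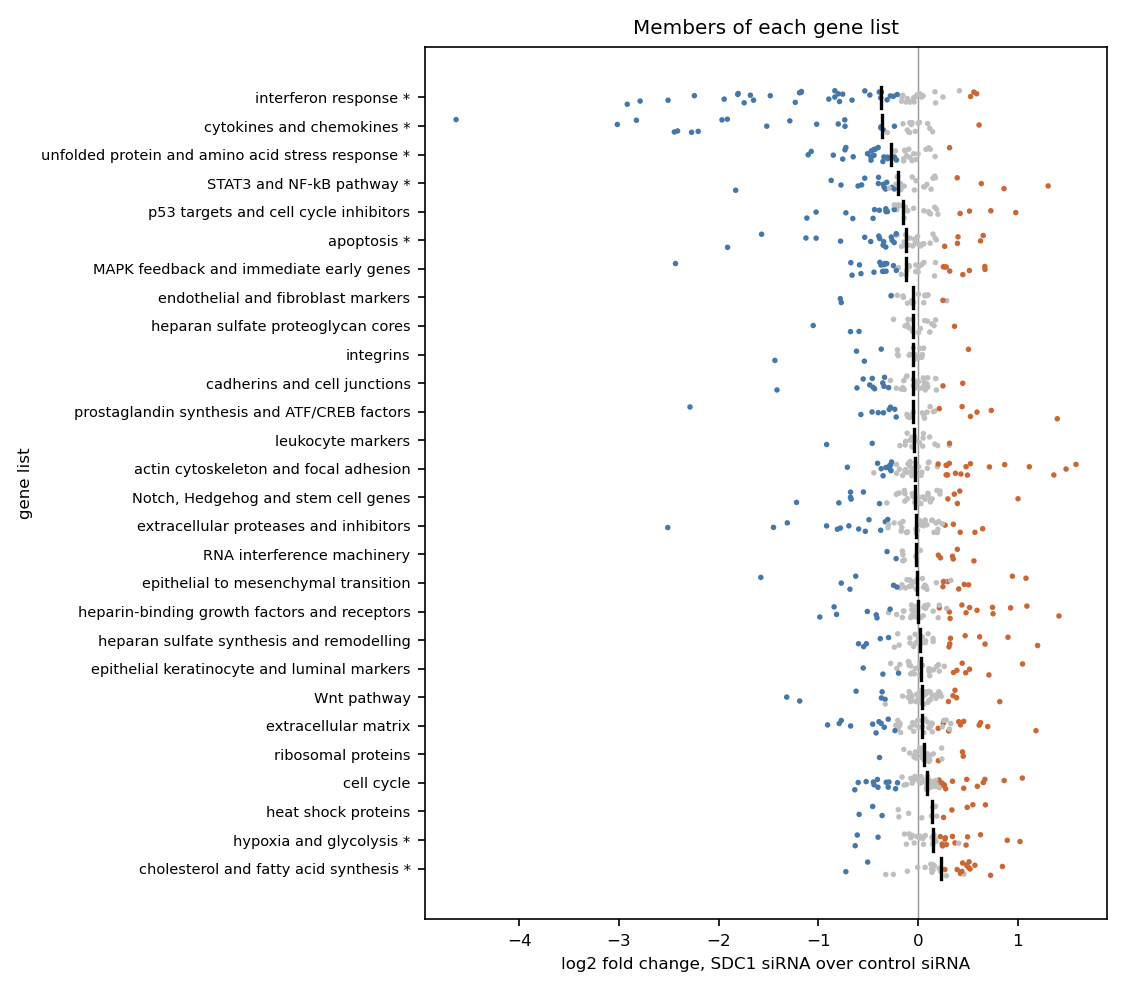
Log2 fold change (horizontal axis, SDC1 siRNA over control siRNA) of every measured member of 28 gene lists (vertical axis), blue where lower, orange where higher and grey where not past 0.05, with a black bar at each list's median and an asterisk for a camera adjusted p below 0.05. The interferon list, at a median of -0.37, and the cholesterol list, at 0.23, form the ends of the order.

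Over the 29 lists, 8 passed camera at the preset correlation, 6 lower and 2 higher. With an estimated correlation 0 passed after adjustment, and 4 had an unadjusted p under 0.05. As a sign of RNA quality, the 3' minus 5' signal of the actin control differed by 0.04 (exact permutation p = 0.8) and that of GAPDH by 0.01 (exact permutation p = 0.7), where 0.1 is the smallest p that 3 against 3 arrays allow. Both signals, relative to the probe sets' medians, moved with the spike-in batch. They were positive in every array of the first batch and negative in every array of the second. Among changed genes with several probe sets, 67.7% had all of them in the same direction, so a single gene's value can depend on which probe set is read.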

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

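The comparison of directions below and its split by spike-in batch were chosen only after the counts were seen. Probe sets outside the comparison of named genes also changed. Of 11721 array features without a gene name in the annotation used here, 1178 (10.1%) passed limma's threshold, 786 of them higher and 392 lower after SDC1 siRNA, against 22.6% of features tied to a single gene. Of 1801 features tied to several genes, 371 (20.6%) passed. Within groups of 3 no outlier test of single arrays was run, and only 1 contrast was made.

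Called features without a name were more often higher than called features of a single gene, 66.7% against 46.7% (Fisher's exact test over features, which are not independent replicates, p = 1.33e-38). With each array centred on its median the shares were 64.6% and 45.6%. Brightness as the whole cause is argued against by shares that still differed by 8.65, 20.6 and 13.3 percentage points within the 3 classes, dimmest to brightest, though the classes are coarse. A processing batch stays open, since each spike-in batch holds only 1 array of one of the groups. Of unnamed features called within the first batch 53.4% were higher there and 53.4% in the second, against 43.8% of such single-gene features in the second. Of those called within the second 61.7% were higher there and 60% in the first, against 45.95% of such single-gene features in the first. Non-coding or intronic transcripts that rise with SDC1 silencing are an untested biological hypothesis.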

How the results depend on the processing

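Across the 18 alternatives that give it a value the SDC1 fold change stayed between -2.70 and -2.28 (highest adjusted p = 8.89e-05). The batch block, the class from all 6 arrays, 1 random probe set per gene and the 2-fold threshold were chosen after seeing the data. The number of changed genes ranged from 4429 with 1 random probe set per gene to 6794 at an adjusted p under 0.1, and from 4486 to 5067 without each array in turn. A fold threshold lowered it by construction, to 1385 genes and 3516 probe sets at 1.5-fold and to 362 and 887 at 2-fold. Replicate numbers did not pair the arrays, as same-numbered arrays deviated from their group means with r of -0.01, 0.04 and 0.09, and the replicate block called 5460 genes. Of 2573 values of 143 named genes besides SDC1, 2518 kept direction and side of the threshold, 29 lost the call, 10 gained it and 16 changed sign, and 112 genes kept both throughout. Centring each array on its median turned no group difference of the hybridisation and poly-A controls. It cannot move the 3' minus 5' differences, which lie within an array. Signal over background is not in the values, so what it limits was not assessed.

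With an estimated correlation 0 lists passed (4 at an unadjusted p under 0.05), with adjusted p of 0.292 for interferon, cytokine, STAT3 and NF-kB and apoptosis genes, 0.081 for the unfolded protein response, 0.620 for cholesterol and 0.543 for hypoxia genes. The estimated correlation was 0.634 for cholesterol genes. It was 0.00465 for apoptosis genes and -0.00588 for unfolded protein genes, both below the preset 0.01. For the unfolded protein list camera's unadjusted p still rose, from 2.645e-08 at the preset to 0.00279. A larger correlation is thus not the cause for every list. Camera with an estimated correlation also takes its p from the few residual degrees of freedom of the 6 arrays. At the preset it uses the number of genes tested. The weaker p with the estimated setting can thus not be read as an effect of correlation alone. Fry, which does not compare a list with other genes, passed 21, 13 lower and 8 higher. Its adjusted p crossed the threshold for the lists of proteoglycan cores (0.0165), heparan sulfate synthesis (0.00249), integrins (0.00917), actin (0.00952), cadherins (0.00283), epithelial markers (0.0349), proteases (0.00391), Notch (0.00845), growth factors (0.0166), MAPK (0.00136), p53 (0.00136), RNA interference (0.0206), heat shock (0.00525) and ribosomal proteins (0.00391), was 0.0824 for cholesterol, and turned the direction for transition genes (0.333) and the Wnt list (0.915). Averaging all probe sets gave 0.0221 for MAPK and 0.0132 for p53 genes. The class from all 6 arrays gave 0.0378 for cadherins. A random probe set per gene gave 0.0371 for cadherins, 0.0300 for MAPK and 0.0374 for p53 genes and turned the direction for transition genes (0.923) and RNA interference (0.896). Leaving out arrays in turn, adjusted p ran from 0.0473 to 0.169 for cadherins, 0.0118 to 0.0547 for apoptosis and 0.653 to 0.982 for transition genes, whose direction turned without control replicate 3. The apoptosis call was lost without SDC1 siRNA replicate 3 and the cadherin call gained without control replicate 2. Other causes were not tested.

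Signs changed under 1 random probe set per gene, which read a dimmer probe set except for NRG1, for ITGA1 (0.22), ADAM19 (0.028), IL1A (0.21), LRP6 (0.033), NRG1 (-0.21), ACTA2 (0.21), NOTCH1 (0.16) and EXT1 (0.0098). NOTCH1 was at 0.050 with all probe sets averaged, RPL7 at 0.13 with _x_at probe sets and RGS5 at -0.044 with the class from all 6 arrays. Without single arrays SDC3 ran from -0.048 to 0.13, MMP2 from -0.00071 to 0.13 and MMP9 from -0.019 to 0.13, none of them called. A random probe set per gene also ended the calls of CD44, ACTG2, OCLN, GATA3, TNFAIP2, DKK3, HPGD, TNRC6A, AGO4, ELOVL6, RPL35, RGS5 and MYL9. Averaging all probe sets ended the calls of ITGA1, PRKRA, RPL22, RPL7, ACTA2 and RGS5. It also shrank fold changes, to -3.43 for CXCL5, -0.19 for HMGA2, -0.42 for LRP6, -1.10 for IL1A, -1.32 for TBC1D7, -1.11 for IL6R, -0.57 for DVL3, -0.64 for ADAM19, -0.39 for EREG, 0.83 for ACTG2, 0.66 for ATF2 and 0.90 for TOP1MT. RPL35 lost its call with any array left out and with the replicate block (adjusted p = 0.0520), and RGS5 without SDC1 siRNA replicate 2.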

Other observations

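The gene families and single genes of the opening paragraphs, the array splits, the RNA integrity test and the question of the control siRNA were chosen only after the results were seen.

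Annexins, calcium-dependent membrane-binding proteins, were lower after SDC1 siRNA. Among 125 families formed from shared symbol stems with at least 15 measured genes, they were the only family past camera's threshold, with 6 of 15 members lower and 0 higher, a median log2 fold change of -0.23 (-0.23 and -0.25 within the spike-in batches) and an adjusted p = 0.0382, against 0.967 with an estimated correlation. ANXA3 fell by 1.52 (SE 0.059), ANXA10 by 1.44 (SE 0.16), ANXA6 by 0.59 and ANXA5 by 0.30.

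Several single genes outside the lists, picked by eye and not tested as groups, also changed. The maintenance DNA methyltransferase DNMT1 rose by 1.40 (SE 0.059, adjusted p = 2.17e-06), while the methylcytosine dioxygenases TET1 and TET3 fell by 1.61 and 1.68. ST8SIA4, which makes polysialic acid, fell by 2.44 (SE 0.10), CMAS, which activates sialic acid, by 1.80 and the sialyltransferase ST3GAL1 by 1.08. The lipopolysaccharide receptor TLR4 was at -1.48, its partner LY96 at -1.26 and STING1, an adaptor of cytosolic DNA sensing, at -1.02. AHR, the aryl hydrocarbon receptor, fell by 0.75 and its partner ARNT by 1.06, and CYP1A1, CYP1B1 and TIPARP, which the receptor can induce, fell by 1.03, 1.12 and 1.02.

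Probe sets of the same gene sometimes changed in opposite directions. Among 2123 genes with at least 2 called probe sets, 227 had calls both ways. A simulation that took a share of 0.05 of these calls as false, each with a random sign, gave about 127. That share was assumed and not estimated from the data. In 22 genes both directions reached 1.5-fold, as in ENSA (-1.15 and 0.74), NUP58 (-1.16 and 0.70), CYRIA (-0.80 and 1.21) and SUN1 (-0.74 and 0.94).

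The real split of the 6 arrays called 5571 genes in limma and was 1 of 10 possible. The highest other called 0 after adjustment and 563 at an unadjusted p under 0.05. Each other split mixes the groups, so any group difference widens its spread and lowers its count. The low counts thus bear little on chance, and 10 splits are too few for a share under 0.05. The spike-in batch as a block left 5245 genes, and fold changes from the disjoint batches correlated across genes (r = 0.824, genes not being independent replicates), which argues against batch as the whole cause. The group difference in the 3' to 5' controls has an upper 95% bound of 0.286, below the median called change of 0.392. This argues against RNA integrity as the whole cause. Called changes went down to 0.17 and only actin and GAPDH were read, so a part in the smaller changes cannot be excluded. A copy number difference would make neighbouring genes move together, and their correlation was 0.07 across genes (permutation p = 0.000999, the smallest that 1000 permutations give), above chance but too small for the whole cause. An effect of the SDC1 loss, or of other targets of the siRNA, may underlie the rest, and a single siRNA cannot part these.

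The fall of interferon-stimulated genes was weighed in the same way. The list's median of -0.371 lay below all of 10000 random lists of the same brightness classes, whose lowest was -0.149, which argues against a normalization shift. Within the spike-in batches the smaller of the falls was -0.386, which argues against batch. Whether the 31 lower members lost expression after SDC1 siRNA or had gained it from the control siRNA, since double-stranded RNA can induce these genes, cannot be told apart without untransfected cells. That SDC1 supports interferon signalling in these cells thus remains a hypothesis.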
